A study of Homo sapiens with 12 samples.

How the data were processed

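RNA of C4-2 cells was hybridised to Affymetrix whole-transcript gene arrays of the Human Gene ST type with 1 channel, 1 sample per array. Per the labels' protocols, cells near confluence were treated for 16 h, total RNA was extracted with Trizol and amplified as cDNA, and the cDNA was labelled with biotin. The 12 arrays form 6 groups of 2 (vehicle, cabazitaxel or docetaxel, in stripped or full serum), and every array was matched to its sample by name.

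The authors deposited 1 table of RMA-normalized values, per the submitters' processing notes, with genes of low expression removed at a threshold not given in the sources used here. RMA corrects background, quantile-normalizes arrays and summarises probes, and usually returns log2 values. The deposited values lie between 17.78 and 6141.3, so they are intensities on a linear scale, although log2 values had been assumed when the tests were fixed. All tests were run on the log2 of the deposited intensity with no pseudocount. The table holds 44629 rows. Through GEO's platform annotation 15835 rows (35.5%) had 1 gene symbol, 0 had several and 28794 were not named here, and rows without a name entered no main test. Symbols were updated through Entrez gene identifiers in a RefSeq table of assembly GRCh38.p14, used for names only. No genome build was used, so no coordinates are given. Where 651 genes had more than 1 row, the row with the highest mean over the 12 arrays stood for the gene, which left 14812 genes. A filter at the median of all rows had been planned for an unfiltered table. The table had fewer rows than the limit set for that, so no filter was applied, and the test without a filter that had been listed as a variation is the same as the one reported.

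Tests used limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, 6 residual degrees of freedom, moderated variances without a trend, two-sided p-values and Benjamini-Hochberg adjustment within each comparison at 0.05. Each taxane was compared with vehicle and with the other taxane in each serum and averaged over both, full with stripped serum in vehicle, and the effect of each taxane between the sera. Errors are the standard errors of the fitted log2 fold change. Median 95% confidence intervals reached 0.13 on either side for averages over both sera and 0.18 within a serum. The submitters' notes name Student's test of drug over control, which is given as the methods' t-test.

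Before the data were examined, 27 gene lists, the genes to be named and the tests were fixed. Lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over 20 lists, and again with an estimated correlation. The fry test of whether a list moves one way was also run. Its p for the G1/S list, cabazitaxel against docetaxel averaged over both sera, was 0.38. Tubulin, histone, drug transport and metabolism, and mitochondrially encoded genes had 0 members named here. Androgen-repressed genes, nuclear-retained long non-coding RNAs and endothelial markers had 3 each. These 7 lists were not tested. The androgen-induced list shares 1 gene, NDRG1, with the hypoxia list. The p53 list shares BAX and BBC3 with the BCL2 family list and SESN2 with the ATF4 list. ATF3 is in both the ATF4 and the immediate early list. Named genes were, per comparison, the 6 largest rises and 6 largest falls among genes that passed and whose groups did not overlap within either serum, leaving out symbols of unnamed loci, small RNAs and similar classes. Where fewer than 3 passed in a direction, the 3 with the smallest p were named. Up to 4 members of each list that passed camera and preset genes were added. Of the preset genes, KLK3, FKBP5, GDF15, CCNB1, PLK1 and AURKA were measured, while TMPRSS2, CDKN1A, TUBB, TUBA1B, TUBB3 and ABCB1 were not named in the table used here. Some preset genes are not reported here. Some genes named beyond this rule (GREB1 with cabazitaxel, PLK2 and ELOVL5 between the sera, and those of pooled comparisons) were chosen after their values were seen. Array means of lists were compared in the same model, with 95% confidence intervals. The overlap of the taxanes' calls, their same-sign counts and their correlation were set against simulated groups without effect that share vehicle arrays, and random lists matched on mean expression (10000 draws) gave percentiles. The simulated overlap of calls and the calls with split vehicle arrays were added after the overlap was seen.

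On simulated data made from these arrays with 200 changed genes, the test of cabazitaxel over both sera recovered 58.8% of changes of 0.3 and 95.2% of changes of 0.6 on the log2 scale among 14812 genes. The test within full serum recovered 28% and 82%, and that of serum in vehicle 28% and 81.3%. A list of 26 genes shifted by -0.3 was called in 20 of 20 runs, and 1 of 380 unchanged lists was called. The simulated genes varied independently, so these runs do not show how often camera calls unchanged lists whose members vary together. Alternatives tried were stricter filters, all rows, quantile or median scaling, a variance trend, the replicate number as a block, each array left out, the arrays of 1 serum alone, and the methods' t-test.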

Results

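Gene expression was measured in C4-2 cells, a line derived from LNCaP prostate cancer cells that grows with little androgen. Cells were exposed for 16 h to 1 nM cabazitaxel, 1 nM docetaxel or the ethanol vehicle. Both drugs are taxanes, which bind microtubules and keep them from depolymerising, and cabazitaxel is docetaxel with 2 hydroxyl groups replaced by methoxy groups. Each treatment was given in full serum and in serum treated with charcoal and dextran, called stripped serum here. Stripping removes steroids including androgens, and also other molecules that bind charcoal. The 6 groups had 2 arrays each, 12 in all, and this number limits the precision of every value. Replicate arrays correlated with Pearson's r between 0.994 and 0.995 over 14812 named genes. Arrays of different groups correlated nearly as highly, with a median r of 0.9933 against 0.9946 within groups. The median intensity per array lay between 31.7 and 32.5. The first principal component held 25.2% of the variance and separated the sera, with all stripped-serum arrays on one side and all full-serum arrays on the other. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No scan dates or slides are given in the sources used here, so batches could not be examined.

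Cabazitaxel lowered genes of the G1/S transition and DNA replication and raised a small set of p53 target genes (4 cabazitaxel arrays against 4 vehicle arrays, averaged over both sera). All 26 measured members of the G1/S and DNA replication list had negative log2 fold changes, with a median of -0.34. Of these, 17 fell in limma over all genes and 26 adjusted over the list alone. CLSPN, which encodes an adaptor for activation of the checkpoint kinase CHEK1, fell (log2 fold change -0.61 ± 0.06 SE, 1.53-fold lower, limma adjusted p = 0.00588), and a second row for it had -0.46. GINS2, a subunit of the replicative helicase, had -0.59 ± 0.07 (adjusted p = 0.00782), and the DNA exonuclease EXO1 had -0.55 ± 0.06 (adjusted p = 0.00588). MCM10, needed to start replication, had -0.53 ± 0.06 and CDC6, which loads the helicase at origins, had -0.49 ± 0.05 (both adjusted p = 0.00588 in limma). Outside the list, WDR76 changed by -0.54 ± 0.07 (limma adjusted p = 0.0108) and RAD54L, a factor of homologous recombination, by -0.53 ± 0.09 (limma adjusted p = 0.0375).

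The p53 target list rose with cabazitaxel, with positive log2 fold changes in 16 of 16 members and a median of 0.21. TP53INP1, a p53-induced regulator of cell death and autophagy, rose most (0.54 ± 0.05, 1.46-fold, limma adjusted p = 0.00588). GDF15, which encodes a secreted stress cytokine, rose by 0.52 ± 0.09 (1.43-fold, adjusted p = 0.0446), and the polo-like kinase gene PLK2 rose by 0.37 ± 0.05 (1.29-fold, adjusted p = 0.0249). These were the 3 members that passed over all genes, and 12 rose adjusted over the list alone. SESN1, a stress-responsive regulator of TORC1, had 0.36 ± 0.06 and did not pass (limma adjusted p = 0.0521). The only other gene that rose was KDM5B, a histone H3 lysine demethylase (0.33 ± 0.06, limma adjusted p = 0.0464).

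With cabazitaxel, mitotic genes had values on both sides of 0. Of 34 measured members of the G2/M and mitosis list, 12 had positive and 22 negative log2 fold changes, with a median of -0.09. HJURP, the chaperone of the centromeric histone CENPA, was the only member that fell over all genes (-0.24 ± 0.04, limma adjusted p = 0.0464), and 4 fell adjusted over the list alone. CDK1 had -0.25 ± 0.04 (adjusted p = 0.0549), AURKB -0.29 ± 0.07 (adjusted p = 0.144) and TOP2A -0.19 ± 0.05 (adjusted p = 0.24). CCNB1 had 0.13 ± 0.06 (adjusted p = 0.577), PLK1 0.04 ± 0.05 (adjusted p = 0.883) and AURKA 0.01 ± 0.08 (adjusted p = 0.991). None of these last 6 genes passed in limma.

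In all, 47 of 14812 genes passed in limma with cabazitaxel, 4 higher and 43 lower, and 1214 had an unadjusted p under 0.05, where chance gives 741. In camera, which compares a list with all other genes, the G1/S list had adjusted p = 6.19e-54 and the p53 list 2.49e-17, and both passed with an estimated correlation (adjusted p = 0.00264 and 0.00167). The G2/M list had camera adjusted p = 4.46e-06 and did not pass with an estimated correlation (adjusted p = 0.297 with an estimated correlation). Cholesterol synthesis genes had a median of -0.07 over 15 members, and 0 passed in limma over all genes or adjusted over the list alone. The 4 members with the smallest p had -0.14 ± 0.08 (INSIG1, a regulator of sterol sensing), -0.12 ± 0.05 (ACAT2), -0.09 ± 0.05 (SREBF2) and -0.08 ± 0.05 (EBP). That list's camera adjusted p was 0.0424, and adjusted p = 0.205 with an estimated correlation. Leaving out any 1 of the 8 arrays gave between 11 and 33 genes. CLSPN, GINS2, EXO1, MCM10, CDC6 and TP53INP1 passed in all 16 alternative tests of this comparison, while WDR76 passed in 11, PLK2 and RAD54L in 7, GDF15 in 6, KDM5B in 5 and HJURP in 4. The 16 include the test without a filter, which repeats the reported test.

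**Figure D1:**
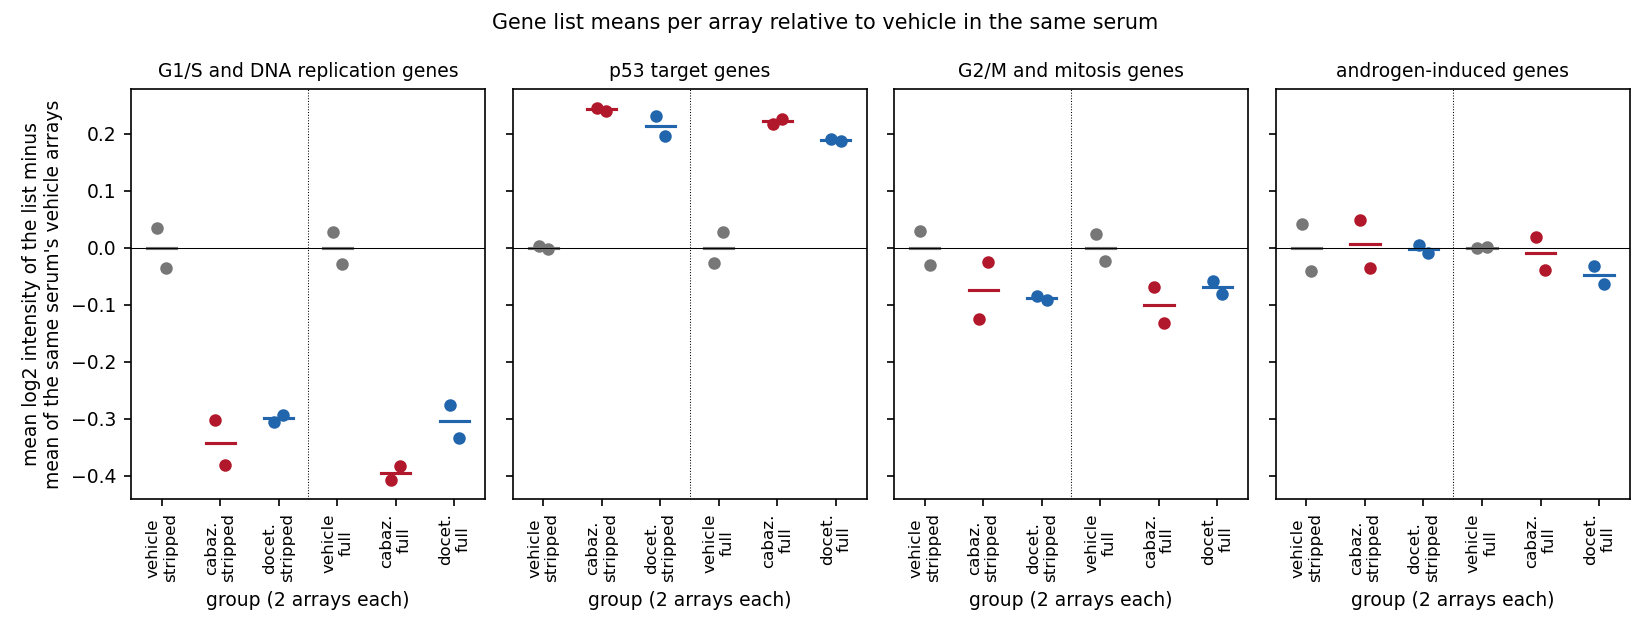
Mean log2 intensity of 4 gene lists on each of the 12 arrays (points, 2 per group), relative to the mean of the vehicle arrays in the same serum; horizontal bars are group means. The G1/S and DNA replication means lie between -0.41 and -0.28 on the 8 taxane arrays, and the p53 target means between 0.19 and 0.25.

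Docetaxel, at the same dose and time, also lowered G1/S and DNA replication genes and raised p53 targets as groups (4 arrays against 4). All 26 measured G1/S and DNA replication genes had negative log2 fold changes, with a median of -0.30, and 4 fell over all genes and 25 adjusted over the list alone. The genes that fell were MCM10 (-0.48 ± 0.06, 1.39-fold lower), FBXO5, an inhibitor of the anaphase-promoting complex (-0.41 ± 0.05), CDC6 (-0.39 ± 0.05), the cyclin gene CCNE2 (-0.34 ± 0.04), the helicase gene MCM6 (-0.34 ± 0.05) and MNS1, known from cilia and sperm flagella (-0.32 ± 0.04). Their limma adjusted p-values lay between 0.0361 and 0.041. TP53INP1 was the only gene that rose (0.45 ± 0.05, 1.37-fold, limma adjusted p = 0.0361). Of the p53 targets, 15 of 16 had positive values, with a median of 0.19, and 1 rose over all genes and 11 adjusted over the list alone. SPATA18, a p53-induced gene of mitochondrial quality control, had 0.34 ± 0.06 (adjusted p = 0.0996), SESN1 0.30 ± 0.06 (adjusted p = 0.182), RPS27L 0.22 ± 0.04 (adjusted p = 0.158) and GDF15 0.31 ± 0.09 (adjusted p = 0.508), none of which passed in limma. Outside the lists, MYNN, a zinc finger gene, had 0.28 ± 0.05 and did not pass (limma adjusted p = 0.123).

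With docetaxel 7 genes passed in limma, 1 higher and 6 lower (0 with the replicate number as a block), and 849 had an unadjusted p under 0.05. The camera adjusted p was 2.38e-52 for the G1/S list and 8.05e-19 for the p53 list (adjusted p = 0.00287 and 0.00131 with an estimated correlation). The G2/M list had a median of -0.09 and camera adjusted p = 7.15e-06, and adjusted p = 0.396 with an estimated correlation. In it 0 genes passed in limma over all genes and 2 fell adjusted over the list alone. HJURP had -0.26 ± 0.04 (limma adjusted p = 0.0744), KIF2C -0.27 ± 0.08, CDK1 -0.22 ± 0.04 and KIF11 -0.17 ± 0.05, and CCNB1 had 0.10 ± 0.06. The count of 7 genes fell to between 0 and 3 when any 1 of the 8 arrays was left out, and testing every row of the table, named or not, gave 0.

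Direct comparison of the related drugs at 1 nM and 16 h found no gene that passed. In limma 0 genes passed for cabazitaxel against docetaxel averaged over both sera (4 arrays against 4), the smallest adjusted p was 0.999, and 638 genes had an unadjusted p under 0.05, where chance gives 741. The 95% confidence interval of the difference lay within 1.5-fold in either direction for 14798 genes (99.9%) and within 2-fold for 14811. The largest log2 fold changes against vehicle were -0.61 and 0.54 with cabazitaxel, and -0.48 and 0.45 with docetaxel. A bound of 1.5-fold is about as wide as these drug effects, so it cannot show that the taxanes act alike. The G1/S genes were lower with cabazitaxel in 23 of 26 cases, with a median difference of -0.05. GINS2 differed by -0.24 ± 0.07, MCM5 by -0.17 ± 0.07, CLSPN by -0.17 ± 0.06 and EXO1 by -0.16 ± 0.06, and 0 members passed over all genes or adjusted over the list alone. The list's camera adjusted p was 2.33e-05, but it did not pass with an estimated correlation (adjusted p = 0.613 with an estimated correlation), and the list's array mean differed by -0.07 with a 95% interval from -0.13 to 0.0011. The p53 targets differed by 0.03 in the array mean (95% interval from -0.0019 to 0.06, camera adjusted p = 0.565). The G2/M genes differed by -0.0085 (95% interval from -0.08 to 0.06). GDF15 was higher with cabazitaxel by 0.21 ± 0.09 and did not pass (limma adjusted p = 0.999). The smallest p-values belonged to TEKT4P2 (0.27 ± 0.06), PRR15 (0.26 ± 0.05), LDLRAD4-AS1 (0.23 ± 0.05), ZNF674-AS1 (-0.25 ± 0.06), ANKRD42 (-0.22 ± 0.05) and HTR7P1 (-0.19 ± 0.04), none of which passed. A second row for TEKT4P2 differed by 0.02.

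TP53INP1 rose and CCNE2, CDC6, FBXO5, MCM10, MCM6 and MNS1 fell with each taxane when the calls were set side by side. Independent lists of these sizes would share 0.00027 genes among those that rose (4 and 1) and 0.0174 among those that fell (43 and 6), a value that leaves out the shared vehicle arrays. In 50 simulations without any effect against shared vehicle arrays, lists of these sizes shared 0.18 and 1.8 genes on average and at most 1 and 6, as many as observed. All 47 genes called with cabazitaxel had the same sign with docetaxel, with a median log2 fold change of -0.37 with cabazitaxel and -0.30 with docetaxel, where the simulations gave 43.5 genes with the same sign on average and at most 46. Genes varied independently in the simulated groups. If the called genes vary together, the count would spread more widely, so 47 against at most 46 decides nothing. With the vehicle arrays split between the drugs, limma called 8 or 1 genes with cabazitaxel, all with the same sign with docetaxel, and 0 with docetaxel, so the calls had no overlap. The effects of both taxanes were measured against the same 4 vehicle arrays. Over all 14812 genes, which are not independent replicates, the log2 fold changes of the taxanes correlated with r = 0.637, where simulated drug groups without any effect against shared vehicle arrays gave 0.497. The covariance was 0.00395 against 0.00247 simulated, a difference of 0.00148. With the vehicle arrays split between the drugs, the covariance was 0.00151 or 0.00168 and r was 0.175 or 0.198. The same sign was found for 70.1% of genes, against 66.5% simulated.

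**Figure D2:**
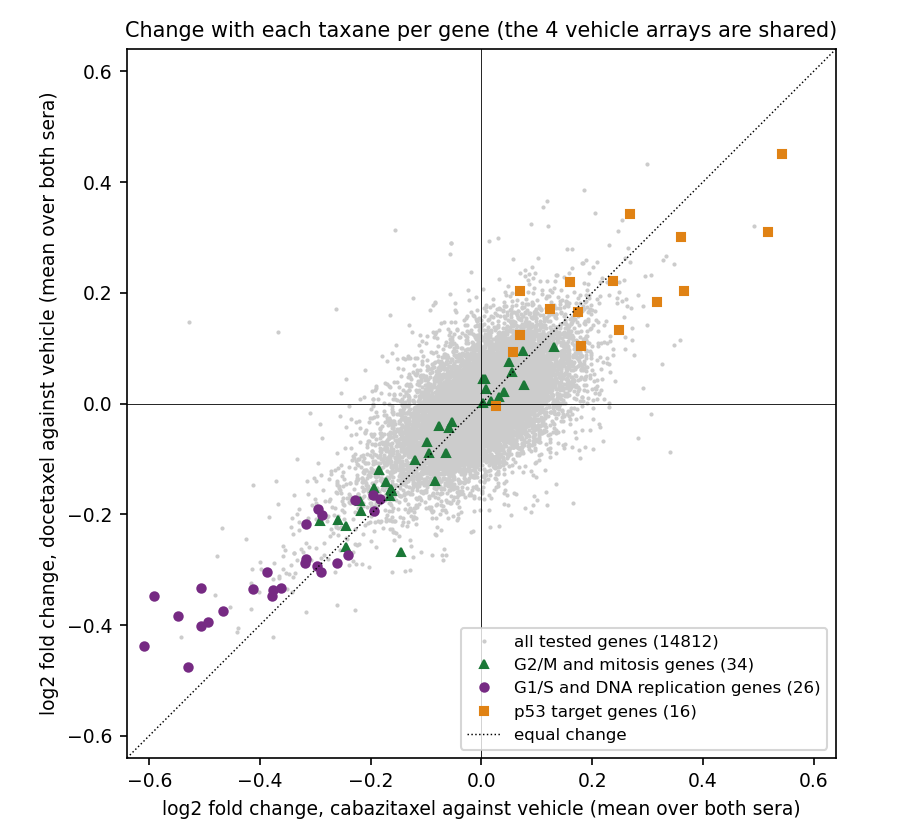
Log2 fold change with docetaxel against that with cabazitaxel for 14812 genes (grey points), each averaged over both sera, with members of 3 gene lists coloured and a dotted line of equal change. The 26 G1/S and DNA replication genes lie in the lower left, with medians of -0.34 for cabazitaxel and -0.30 for docetaxel; both axes share the 4 vehicle arrays.

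Within stripped serum (2 arrays against 2), no single gene passed with either taxane. With cabazitaxel, the G1/S and DNA replication genes had a median of -0.33 and the p53 targets 0.23. MCM10 had -0.57 ± 0.08 and DTL, a substrate receptor of an ubiquitin ligase that acts at replication forks, -0.55 ± 0.09, while TP53INP1 had 0.48 ± 0.07 and MYNN 0.55 ± 0.07 (each limma adjusted p = 0.175). GDF15 had 0.63 ± 0.12 (limma adjusted p = 0.261). With docetaxel, the medians were -0.29 and 0.21, with TP53INP1 at 0.52 ± 0.07 and MNS1 at -0.42 ± 0.06 (each limma adjusted p = 0.234), MYNN at 0.49 ± 0.07 (adjusted p = 0.258) and FBXO5 at -0.45 ± 0.07 (adjusted p = 0.296).

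As groups these lists passed in stripped serum. For cabazitaxel the camera adjusted p was 7.63e-44 for the G1/S list and 3.32e-14 for the p53 list (adjusted p = 0.0047 and 0.00299 with an estimated correlation). For docetaxel it was 8.54e-40 for the G1/S list, and the G1/S and p53 lists had adjusted p = 0.00612 and 0.00406 with an estimated correlation. Over all genes 0 members passed in limma, while 25 G1/S genes fell with cabazitaxel and 24 with docetaxel adjusted over the list alone, and 11 and 9 p53 targets rose. The G2/M list had a median of -0.06 with cabazitaxel (camera adjusted p = 0.000708, and adjusted p = 0.677 with an estimated correlation) and -0.12 with docetaxel (camera adjusted p = 5.38e-05, and adjusted p = 0.549 with an estimated correlation). Its mean with cabazitaxel, -0.07, became -0.04 without vehicle stripped replicate 1 (adjusted p = 0.321), -0.02 without cabazitaxel stripped replicate 1 (adjusted p = 0.641) and -0.12 without cabazitaxel stripped replicate 2. With docetaxel the list did not pass without vehicle stripped replicate 1 (mean -0.06, adjusted p = 0.137). The 0 genes that limma called set against 871 with cabazitaxel and 684 with docetaxel at an unadjusted p under 0.05. The methods' t-test gave 0 genes after adjustment for both drugs, with 684 and 695 unadjusted. Cabazitaxel against docetaxel gave 0 genes in limma (547 unadjusted) and 0 by the methods' t-test (661 unadjusted). The 95% interval of this difference lay within 1.5-fold for 14678 genes (99.1%), a bound too wide to show that the taxanes act alike.

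Within full serum (2 arrays against 2), cabazitaxel changed 3 genes. TP53INP1 rose by 0.60 ± 0.07 (1.52-fold), CLSPN changed by -0.78 ± 0.09 (1.72-fold lower) and MCM6 by -0.51 ± 0.06 (1.43-fold lower), each with limma adjusted p = 0.0436. A second row for CLSPN had -0.54. MNS1 (-0.44 ± 0.06, adjusted p = 0.0508), CDC6 (-0.55 ± 0.08) and CCNE2 (-0.43 ± 0.06, both adjusted p = 0.0522) did not pass in limma. The G1/S list had a median of -0.34, with 2 members that fell over all genes and 25 adjusted over the list alone. The p53 list had a median of 0.21, with 1 member that rose over all genes and 7 adjusted over the list alone. Camera gave adjusted p = 3.05e-36 and 4.25e-09 for these lists (adjusted p = 0.00788 for each with an estimated correlation). The G2/M list had a median of -0.11 with camera adjusted p = 0.0005, and adjusted p = 0.456 with an estimated correlation. It did not pass without cabazitaxel full replicate 2 (adjusted p = 0.108). The count of 3 had 1359 genes at an unadjusted p under 0.05 beside it, and fell to 0 with any 1 of the 4 arrays left out, in a fit of the 6 full-serum arrays alone, and by the methods' t-test (905 unadjusted).

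With docetaxel in full serum, the G1/S genes had a median of -0.30 and the p53 targets 0.19, and no single gene passed. MCM10 had -0.48 ± 0.08, CLSPN -0.47 ± 0.09, CCNE2 -0.39 ± 0.06, TP53INP1 0.38 ± 0.07, the transcription factor gene TBX5 0.33 ± 0.06 and the neuropeptide gene GRP 0.32 ± 0.07 (each limma adjusted p = 0.666), and a second row for CLSPN had -0.31. Limma called 0 genes with 793 at an unadjusted p under 0.05, and the methods' t-test 0 with 728 unadjusted. Camera adjusted p was 1.43e-35 and 1.08e-11 for the G1/S and p53 lists (adjusted p = 0.00829 and 0.00525 with an estimated correlation), and 24 and 4 members passed adjusted over the list alone. The G2/M list had a median of -0.06 (camera adjusted p = 0.00654, and adjusted p = 0.541 with an estimated correlation), and did not pass without vehicle full replicate 1 (mean -0.05, adjusted p = 0.156). All 6 neuroendocrine markers measured had positive values, with a median of 0.11. Among them were CHGA at 0.16 ± 0.08, INSM1 at 0.12 ± 0.11, SYP at 0.12 ± 0.10 and NCAM1 at 0.11 ± 0.09. None passed over all genes or adjusted over the list alone, a second row for SYP had -0.03, and the list's camera adjusted p was 0.0232, with adjusted p = 0.369 with an estimated correlation. The neuroendocrine list, with a mean of 0.10, did not pass without vehicle full replicate 1 (mean 0.11, adjusted p = 0.149), vehicle full replicate 2 (mean 0.10, adjusted p = 0.0594) or docetaxel full replicate 2 (mean 0.06, adjusted p = 0.559). With cabazitaxel in full serum all 6 of these markers were also positive, with a median of 0.08 and a mean of 0.11, and the list did not pass (camera adjusted p = 0.0558).

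In full serum, cabazitaxel against docetaxel gave 0 genes in limma (917 unadjusted, smallest adjusted p = 0.711) and 0 by the methods' t-test (709 unadjusted). The difference lay within 1.5-fold by its 95% interval for 14650 genes (98.9%), a bound too wide to show that the taxanes act alike. CLSPN differed by -0.31 ± 0.09, EXO1 by -0.28 ± 0.09, GINS2 by -0.25 ± 0.10 and MCM6 by -0.20 ± 0.06, and none passed. The G1/S genes were lower with cabazitaxel in 22 of 26 cases (median -0.07, camera adjusted p = 0.00102, and adjusted p = 0.644 with an estimated correlation). The list did not pass without cabazitaxel full replicate 1 (adjusted p = 0.146) or docetaxel full replicate 1 (adjusted p = 0.262). In stripped serum that list had camera adjusted p = 0.161.

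Full serum, compared with stripped serum in vehicle-treated cells (2 arrays against 2), raised androgen-induced genes. Of 17 measured members, 13 rose over all genes and 15 adjusted over the list alone, 16 had positive values, and the median log2 fold change was 0.62. KLK2 rose by 1.31 ± 0.12 (2.47-fold, limma adjusted p = 0.000595) and KLK3, which encodes prostate-specific antigen, by 0.86 ± 0.10 (1.82-fold, adjusted p = 0.00323). C1orf116 rose by 1.00 ± 0.07 (2.01-fold, adjusted p = 0.000135), the ubiquitin ligase gene HERC3 by 0.85 ± 0.07 (adjusted p = 0.000216) and FKBP5, a co-chaperone of steroid receptors, by 0.78 ± 0.09 (1.71-fold, adjusted p = 0.0025). MPHOSPH9, PTGER4, STEAP4 and ORM1 did not pass, and ORM1 had -0.18. The list's camera adjusted p was 9.27e-36 (adjusted p = 0.0031 with an estimated correlation).

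Outside that list, full serum raised ELOVL2, an elongase of polyunsaturated fatty acids (1.30 ± 0.08, 2.46-fold, limma adjusted p = 8.91e-05) and the transcriptional repressor gene SNAI2 (1.27 ± 0.15, 2.41-fold, adjusted p = 0.00308). RHOU rose by 1.02 ± 0.08 (limma adjusted p = 0.000135). SPDEF, a transcription factor of prostate epithelium, rose by 0.97 ± 0.13 and RASSF3 by 0.97 ± 0.08. SYTL2, which acts in vesicle trafficking, was lower by 2.36-fold (-1.24 ± 0.07, limma adjusted p = 4.84e-05). Also lower were CBLN2 (-0.89 ± 0.07), the sucrase-isomaltase gene SI (-0.89 ± 0.11), ARHGEF26-AS1 (-0.86 ± 0.12), SOWAHB (-0.75 ± 0.09) and OCLNP1 (-0.75 ± 0.12), with limma adjusted p-values up to 0.0194. PLK2 (0.71 ± 0.08, adjusted p = 0.002) and the fatty acid elongase gene ELOVL5 (0.69 ± 0.12, adjusted p = 0.0196) also rose, and GDF15 had 0.57 ± 0.12 without passing (adjusted p = 0.0842). In all 128 genes passed in limma, 84 higher and 44 lower in full serum, with 1195 at an unadjusted p under 0.05. Any 1 of the 4 arrays left out gave between 37 and 75 genes, and the methods' t-test gave 0 after adjustment (928 unadjusted).

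No gene of either proliferation list passed between the sera in vehicle (2 arrays against 2). The G1/S list had a median of 0.01 (camera adjusted p = 0.449). In the G2/M list 28 of 34 members had positive values, with a median of 0.03. KIF20A had 0.32 ± 0.08 (limma adjusted p = 0.119), CDK1 0.23 ± 0.06 (adjusted p = 0.188), AURKB 0.18 ± 0.09 and BIRC5 0.15 ± 0.08. In it 0 genes passed over all genes in limma or adjusted over the list alone, and the camera adjusted p was 0.036, with adjusted p = 0.709 with an estimated correlation. The p53 targets had a median of 0.03 (camera adjusted p = 0.465), with PLK2 as the 1 member that rose over all genes and 2 adjusted over the list alone.

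**Figure D3:**
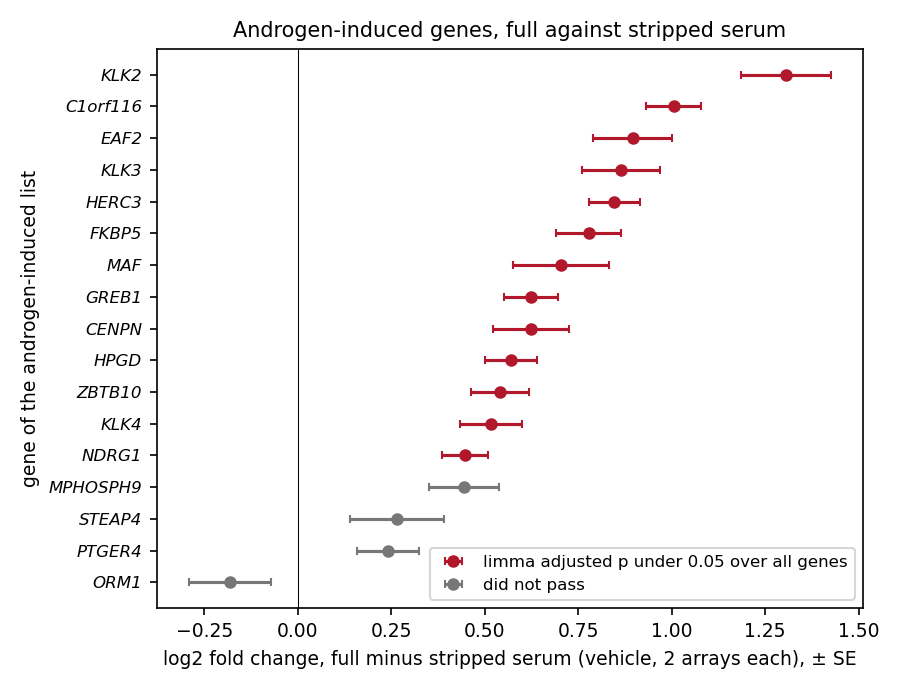
Log2 fold change of the 17 measured androgen-induced genes in vehicle-treated cells, full minus stripped serum (points, 2 arrays per group; bars, SE), with genes that passed in limma in red. KLK2 lies highest at 1.31 and ORM1 lowest at -0.18.

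No androgen-induced gene passed over all genes with either taxane. The array mean of the list differed from vehicle by -0.0014 with cabazitaxel (95% interval from -0.07 to 0.07, camera adjusted p = 0.993) and by -0.03 with docetaxel (95% interval from -0.09 to 0.04, camera adjusted p = 0.317), averaged over both sera. KLK3 had -0.04 ± 0.07 with cabazitaxel (limma adjusted p = 0.939) and FKBP5 -0.04 ± 0.06 (adjusted p = 0.922). GREB1 was the 1 member that rose with cabazitaxel adjusted over the list alone, and 0 members passed with docetaxel in limma.

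The taxane effects were also compared between the sera. The effect of cabazitaxel on the G1/S genes differed by -0.05 between full and stripped serum in the array mean, with a 95% interval from -0.19 to 0.08, and that on the p53 targets differed by -0.02 (from -0.09 to 0.05). For docetaxel the G1/S difference was -0.0047 (from -0.14 to 0.13). RGPD3 had the smallest p, with a difference of -0.76 ± 0.09 in the effect of cabazitaxel, full minus stripped serum, and did not pass (limma adjusted p = 0.0579). MYNN (-0.56 ± 0.11), RIMBP3C (-0.62 ± 0.12), TEX48 (0.91 ± 0.19), RNF157-AS1 (0.43 ± 0.10) and POU5F1B (0.34 ± 0.08) each had limma adjusted p = 0.836. For docetaxel the smallest p-values belonged to LEFTY1 (-0.65 ± 0.13), SHROOM1 (-0.53 ± 0.10), SPATC1 (-0.44 ± 0.09), NPFFR1 (0.62 ± 0.12), GRP (0.43 ± 0.10) and PSD2 (0.36 ± 0.08), none of which passed. Limma called 0 genes for cabazitaxel (879 at an unadjusted p under 0.05) and 0 for docetaxel (525), and no list passed camera (smallest adjusted p = 0.515 and 0.432). The median 95% interval of these differences per gene reached 0.26 on either side.

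Of the other gene groups, none passed camera with either taxane averaged over both sera. With cabazitaxel, the list medians and camera adjusted p-values were 0.01 and 0.925 for microtubule-associated genes, 0.01 and 0.833 for BCL2 family and caspase genes, and -0.01 and 0.833 for genes of ATF4 and the unfolded protein response. Immediate early genes had 0.03 and 0.198, NF-kB targets 0.01 and 0.993, and interferon-stimulated genes 0.0094 and 0.833. Hypoxia and glycolysis genes had 0.0021 and 0.503, fatty acid synthesis genes -0.04 and 0.287, heat shock genes -0.02 and 0.868, and ribosomal protein genes -0.02 and 0.833. Of the cell type markers, luminal epithelial genes had -0.0072 and 0.993, basal epithelial genes 0.0078 and 0.993, neuroendocrine genes 0.04 and 0.287, fibroblast genes -0.02 and 0.859, and leukocyte genes 0.05 and 0.287. In limma 0 members of these lists passed over all genes or adjusted over the list alone. With docetaxel the lowest camera adjusted p among them was 0.0994, for the neuroendocrine markers, and cholesterol synthesis genes had 0.163.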

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

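None of the tests given here was chosen after its result was seen. Rows of the table without a gene name enter none of the comparisons of genes, and some of them changed when every row was tested in limma. With cabazitaxel averaged over both sera, 25 of the 52 rows that passed among 44629 had no name here, 6 higher and 19 lower, with log2 fold changes from -1.15 to 0.77. Between full and stripped serum in vehicle, 55 of the 134 rows that passed had no name here, 41 higher and 14 lower in full serum, with log2 fold changes from -1.19 to 1.86.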

How the results depend on the processing

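The filter at the median, the mean over 3 treatments and the pooling of both taxanes were chosen after seeing the data. Of 180 counts of genes recomputed, 136 stayed the same or within 1.5 times the reported count. Reported counts of 0 that stayed 0 are among the 136, and most comparisons reported 0. The 136 therefore say little about the counts of 47, 7, 3 and 128 genes, whose changes are given below. The 180 counts, and the values of lists and named genes that follow, include the test without a filter, which repeats the reported test and always agrees. Of 356 values of lists, 320 kept their direction and their side of the threshold, among them the G1/S and p53 lists with each taxane averaged over both sera and the androgen-induced list between the sera. Of 3244 values of named genes, 177 no longer passed, 31 newly passed and 87 that passed in neither test changed sign. No result reversed. With any 1 array left out, a lone array is assumed to vary like the other groups. The cause was not tested where a value moved. A filter leaves fewer genes to adjust over and leaving out arrays leaves fewer samples, but whether these account for the changes was not tested. Cabazitaxel averaged over both sera called 47 genes, 95 (8 higher, 87 lower) with a filter at the 75th percentile and 74 (6 higher, 68 lower) with a variance trend. With 1 array left out the count lay between 11 and 33. It was 16 without vehicle stripped replicate 1, 30 and 15 without cabazitaxel stripped replicates 1 and 2, 13 and 11 without vehicle full replicates 1 and 2, and 19 and 12 without cabazitaxel full replicates 1 and 2. Docetaxel called 7 genes, 17 with a filter at the median, 45 at the 75th percentile, 24 with a variance trend and 0 over all rows. It called 3 without docetaxel full replicate 1, 1 without vehicle stripped replicate 1 and 0 without any 1 of the other 6 arrays. Both taxanes pooled against vehicle, which is another comparison and includes the cabazitaxel arrays, gave 62 genes. Within stripped serum, the count of 0 for cabazitaxel became 2 at the 75th percentile and 4 with a variance trend. In full serum, the count of 3 became 9 at the median, 29 at the 75th percentile and 16 with a variance trend. It was 2 (1 higher, 1 lower) after quantile normalization and 0 over all rows, with the same median on each array, in the 6 arrays of full serum, by the methods' t-test (905 unadjusted) and without any 1 of its 4 arrays. Docetaxel in full serum called 0, and 1 without docetaxel full replicate 1. Serum in vehicle called 128 genes, 617 over the 3 treatments and 0 by the methods' t-test (928 unadjusted). It called 75 and 49 without vehicle stripped replicates 1 and 2, and 37 and 46 without vehicle full replicates 1 and 2. The difference between sera in the cabazitaxel effect called 0 genes, and 1 at the 75th percentile.

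The 36 list calls that were lost concerned the G2/M, cholesterol synthesis and neuroendocrine lists and the G1/S list between the taxanes. With an estimated correlation the G2/M list no longer passed with cabazitaxel (mean -0.087), docetaxel (mean -0.079) or serum (mean 0.063), nor the G1/S list between the taxanes (mean -0.067) or the cholesterol list with cabazitaxel (mean -0.055). The cholesterol list also did not pass with filters at the median (mean -0.054) and the 75th percentile (mean -0.052) or after quantile normalization (mean -0.0421), nor without vehicle stripped replicate 1, cabazitaxel stripped replicate 2, vehicle full replicate 2 or cabazitaxel full replicate 1, with means from -0.0684 to -0.0421 over all arrays left out. The G2/M list between the sera also did not pass with filters at the median (mean 0.0634) and the 75th percentile (mean 0.064), after quantile normalization (mean 0.0486), or without vehicle stripped replicate 2 or vehicle full replicate 1, with means from 0.0337 to 0.0932. With the replicate number as a replicate block, 32 genes passed with cabazitaxel, 0 with docetaxel, 4 with cabazitaxel in full serum and 126 between the sera, and no call of a list, or of a named gene in another comparison, changed. Whether the shared numbers pair the samples stays open. Of 15 pairs of groups, 4 had deviations that correlated above 0.1, with r from -0.12 to 0.17, and the labels do not say what the numbers mark. The table used here gives no background level, so signal over background was not analysed.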

Other observations

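The pooled comparisons, the comparison of sera over 3 treatments, the leave-out tests of the G1/S list, the tests of its spread between arrays, of the G2/M array mean, of the androgen-induced genes and of each drug's serum dependence were chosen after the results they bear on were seen. With both taxanes pooled over both sera (8 arrays against 4), 62 genes passed in limma, 6 higher and 56 lower. Genes that rose were TP53INP1 (log2 fold change 0.50 ± 0.05), SESN1 (0.33 ± 0.06), SPATA18 (0.31 ± 0.05), KDM5B (0.30 ± 0.05), PLK2 (0.28 ± 0.05) and MYNN (0.27 ± 0.05). Of the 62 genes, 44 lie outside the G1/S and DNA replication list. These include E2F8, an atypical E2F repressor (-0.41 ± 0.05), the histone chaperone gene ASF1B (-0.43 ± 0.07), the DNA helicase gene BRIP1 (-0.41 ± 0.07) and MASTL, the kinase that restrains phosphatase PP2A in mitosis (-0.37 ± 0.05). CDC7, a kinase that fires replication origins, had -0.31 ± 0.04, the checkpoint kinase gene CHEK1 -0.27 ± 0.04 and CDK1 -0.23 ± 0.04. For these 7 genes the limma adjusted p-values lay between 0.00831 and 0.0332.

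Over the 3 treatments (6 arrays of each serum), 617 genes passed between the sera, 252 higher and 365 lower in full serum, and 126 of the 128 genes called in vehicle were among them with the same sign. The vehicle arrays enter both comparisons, so part of this overlap is built in. Of the 13 members of the ATF4 and unfolded protein response list, 4 fell over all genes and the list did not pass camera (adjusted p = 0.0709). The 4 were PSAT1 (-0.21 ± 0.04) and PHGDH (-0.21 ± 0.05) of serine synthesis, the asparagine synthetase gene ASNS (-0.20 ± 0.03) and STC2 (-0.24 ± 0.05). Adjusted over the list alone 6 fell and 1, SDF2L1 (0.15 ± 0.05), rose. STARD4 (-0.31 ± 0.05), a sterol transporter, and MVD (-0.24 ± 0.06), a mevalonate pathway enzyme, fell in the cholesterol synthesis list (camera adjusted p = 0.00131, and adjusted p = 0.0732 with an estimated correlation). Of the p53 targets, PLK2 rose by 0.74 ± 0.04 and GDF15 by 0.43 ± 0.07, while SESN1 was lower (-0.21 ± 0.05, limma adjusted p = 0.0494). The hypoxia-responsive and androgen-induced gene NDRG1 rose by 0.38 ± 0.04, and the mitotic genes KIF20A and CDK1 by 0.25 ± 0.04 and 0.24 ± 0.04. No difference between the sera was detected for MYNN in the taxane effects. Its mean log2 intensity in stripped serum was 7.37 with vehicle, 7.91 with cabazitaxel and 7.85 with docetaxel, and in full serum 7.26, 7.24 and 7.34, and the difference did not pass for cabazitaxel (limma adjusted p = 0.836) or both taxanes pooled (limma adjusted p = 0.9995).

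Whether other groupings of the arrays give as many genes was examined in a model of drug label and serum, so its counts differ from those of the 6 groups. For cabazitaxel 1 of 34 splits of the 8 arrays, the real one, gave 55 genes or more, and the highest other gave 1. For docetaxel it was 1 of 34, with 19 genes against 0. These results argue against an accident in how single arrays were grouped. So do those for the pooled taxanes (1 of 100 splits, 85 genes against 3) and for serum over the 3 treatments (1 of 100, 676 against 1). Most other splits part replicates of a group, and replicates may be technical. Differences between cultures would then also set the real split apart, so the splits cannot tell these from a drug or serum effect. For cabazitaxel against docetaxel the real count was 0, which any of the 34 splits reaches (34 of 34, highest other 0), so the splits say nothing there.

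For the fall of the G1/S and DNA replication genes with both taxanes, a shift of all genes of that brightness, as a normalization can leave, is argued against by a list mean of -0.34 at percentile 0 of 10000 random lists matched on mean expression, whose central 95% ran from -0.05 to 0.01. A single array that stands apart is argued against by the highest camera adjusted p with any 1 array left out, 8.58e-42 for cabazitaxel and 3.45e-41 for docetaxel. More cells in G2 or mitosis stays open. Against it stand the upper bound of the 95% interval of the G2/M array mean with pooled taxanes, -0.021, and a list mean of -0.08 at percentile 0 of such random lists (central 95% from -0.05 to 0.0095), but within a serum the bounds were 0.0027 (full) and 0.0061 (stripped), members had values of both signs, and the list did not pass with an estimated correlation (adjusted p = 0.297 with cabazitaxel and 0.396 with docetaxel). A hypothesis that also stays open is that both taxanes may lower the share of cells entering S phase, for which no cell counts were analysed here.

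The G1/S genes were lower with cabazitaxel than with docetaxel by -0.07 in the array mean. Spread between arrays that the members share may account for this, since the upper bound of the 95% interval was 0.0011. The list mean lay at percentile 0 of 10000 random lists matched on mean expression (central 95% from -0.026 to 0.019). Random lists need not share the spread of this list, so that percentile does not decide the question. A larger effect of cabazitaxel on all taxane-responsive genes at this dose is also open. Over the 44 genes called with pooled taxanes outside the list, the change was larger with cabazitaxel for 35, by 0.05 on average in the direction of change, with a lower bound of 0.0041. Several of these genes, such as CDC7 and CHEK1, also act in replication or its checkpoint. The test therefore cannot separate a general effect from the G1/S difference itself. All these values come from the same arrays, so they are not independent, and both explanations stay open.

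Hypotheses on serum and androgen signalling were also tested. A taxane response that depends on serum was neither shown nor excluded. In limma 0 genes passed the interaction with both taxanes pooled (650 at an unadjusted p under 0.05, where chance gives 741), 0 with docetaxel (525) and 0 with cabazitaxel (879, smallest limma adjusted p = 0.0579). Such counts decide nothing, since docetaxel in stripped serum also gave 0 genes with 684 unadjusted while its G1/S list passed, and the error of an interaction is wider. A fall of androgen-induced genes with both taxanes in full serum could be neither shown nor excluded, since the array mean differed by -0.03 with a 95% interval from -0.11 to 0.05.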
